A study of Mus musculus with 15 samples.

How the data were processed

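Total RNA from liver and heart of male mice of the C57BL/6J-Tyr strain, 17 weeks old, was measured on one-colour Illumina bead arrays in wild-type mice and in mice homozygous for a mutation of Abcb5. The 15 arrays comprised 4 wild-type livers, 3 mutant livers, 4 wild-type hearts and 4 mutant hearts. By the animal numbers in the labels they came from 8 mice, of which 7 gave both tissues and 1 mutant gave the heart only. Per the labels, RNA was extracted with Trizol and cleaned on a column, and biotin-labelled cRNA was made with an Ambion kit. GenomeStudio 2011.1 is named in the submitters' processing notes. Every sample was a separate mouse within its tissue, so the tests below measure the spread between mice.

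The values analysed were the authors' deposited table of linear intensity per probe for 25697 probes. Which normalization the authors applied was not given in the sources used here. The 2 tissues had clearly been scaled separately: the median intensity was between 113.105 and 113.112 on the liver arrays and between 8.04 and 8.08 on the heart arrays, and none of the liver values but 27.7% to 27.8% of the heart values on each array were below 0. Because the tissues were scaled separately, levels were compared only within a tissue, and the planned contrast of liver with heart in wild-type mice was not run. A second table, of non-normalized intensity, had 15 columns whose names matched no sample label and was used for no comparison here. Of its columns 8 ranked the probes exactly as a heart array did and 0 as a liver array did. The other 7 correlated more with the heart arrays (Spearman 0.838 to 0.860) than with the liver arrays (0.715 to 0.744), so the liver values could not be traced to it. In the values analysed the liver arrays carried the liver transcripts Apoa1 (13450.5 to 16186.7) and Ttr (10154.8 to 13239.8), while Myl2 of heart muscle was between 107.8 and 124.4 there and between 22133.9 and 47565.2 on the heart arrays. Of the probes, 23978 had 1 gene symbol in the platform annotation, 0 had several and 1719 were not listed. The named probes stood for 16593 genes.

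The tests had been planned on the non-normalized table, with background taken from detection p-values. In their place, the background of each array was estimated from its own low values, as their mode (109.8 to 109.9 on the liver arrays and -2.40 to -2.39 on the heart arrays) with the SD of the values below it (2.69 to 2.70 and 2.18 to 2.19). The normexp model was applied with these parameters, an offset of 16 was added and log2 was taken. The authors' scaling was kept. A probe counted as above background on an array when a normal distribution with that mode and SD gave it p below 0.05, and a probe was tested in a tissue when this held on at least 3 of its arrays. On the liver arrays 45.9% to 46.0% of probes were above background, and on the heart arrays 67.3% to 67.4%. The number of arrays limits the precision of all values.

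Genotypes were compared within each tissue with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, mutant minus wild type, Benjamini-Hochberg adjusted p below 0.05). The difference of the genotype effect between the tissues was tested in a single fit of all 15 arrays as the liver change minus the heart change, with the mouse as a random block (duplicateCorrelation, statmod 1.5.0). The pairing of the tissues comes from the animal numbers in the labels, and the estimated correlation between the tissues of a mouse was 0.00788. That fit sets log2 changes of separately scaled tissues against each other, and the liver values rest on a higher background, which shrinks log2 changes of dim probes differently in the tissues. The shared change was described by correlations across genes and by overlaps, against all 35 splits of the 7 mice with both tissues. Gene lists were tested with limma's camera at a preset correlation of 0.01 on 1 probe per gene, the probe with the highest mean in the tissue, with camera at an estimated correlation and with fry as alternatives.

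The 49 gene lists (27 of functions and 22 of cell types), the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The processing of the values was changed afterwards as described above. Each tissue names the 10 genes with the largest increase and the 10 with the largest decrease among probes past the threshold whose mutant and wild-type arrays did not overlap. Directions with fewer such genes were filled up to 10 with the genes of smallest p, which are given by value only. The tissue difference names the 5 genes with the smallest p in each direction, and each list its up to 4 members with the smallest p. Genes named outside this rule are given as list members or as values seen in the data. Lists with fewer than 3 measured members in a tissue were not tested there.

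The limma tests were tried on simulated log2 values, drawn independently for each probe and array after background correction and filter. Those steps and correlated probes were thus not covered. The means and spreads were those of the real probes, and 67 probes were changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold. In liver, over 11942 probes, 35.8%, 79.1% and 97.0% of these were recovered with 7 false calls. In heart, over 18502 probes, 55.2%, 94.0% and 100% were recovered with 9 false calls. For the tissue difference, over 19570 probes, the shares were 16.4%, 73.1% and 100% with 10 false calls. No pair of arrays was identical (0 pairs). Pearson correlations of arrays within a group were between 0.981 and 0.988 in liver and between 0.985 and 0.992 in heart.

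The alternatives were a floor of 16 in place of background correction and offset (above the median of the heart arrays), with and without quantile normalization, median scaling, an offset of 50, no filter and a stricter filter on dim probes, eBayes with trend and robust settings, array weights, a replicate block, a single fit of all arrays, a tissue-difference fit with no mouse block or with a fixed mouse block, and leaving out each array. Quantile normalization belonged to the planned processing of the main values. On the background-corrected values used here, within a tissue and over all 15 arrays, it was added as an alternative after seeing the data. Slides were not used as a block, since the files used here name none, and Abcb5 itself was not analysed here. Leave-one-out fits of the tissue difference kept the mouse correlation estimated from all arrays.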

Results

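Gene expression was measured on Illumina bead arrays in the liver and heart of male mice homozygous for a mutation of Abcb5, which encodes an ATP-binding cassette transporter of the P-glycoprotein family, and of wild-type mice of the same strain and age. The arrays covered 4 wild-type and 3 mutant livers and 4 wild-type and 4 mutant hearts. The comparisons asked which transcripts differ with the genotype in each tissue and whether the difference is shared between the tissues. In liver 11942 probes of 8433 genes were above background and in heart 18502 probes of 12551 genes. Of the 25697 probes, 0 carried the name Abcb5 in the annotation used, so the mutated gene was not analysed here and the genotype labels were not checked by its level.

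In the mutant livers a heme-synthesis gene and clock-controlled genes were higher. Alas1, the rate-limiting enzyme of heme synthesis, rose by 2.41 ± 0.24 on the log2 scale (SE, n = 4 wild-type and 3 mutant mice, 5.31-fold, limma adjusted p = 0.00358). Usp2, a ubiquitin-specific protease under clock control, rose by 2.39 ± 0.18 (5.23-fold, adjusted p = 0.000269), and Ciart, a repressor in the clock, rose by 0.97 ± 0.13 with a further probe past the threshold. Pdk4, the kinase that inhibits pyruvate dehydrogenase, changed by -1.11 ± 0.14 (2.16-fold lower, adjusted p = 0.0179), and the ubiquitin ligase Rnf125 by -1.24 ± 0.15 (2.37-fold lower, adjusted p = 0.0173).

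Of the 11942 probes, 12 passed the threshold in liver, 8 higher (7 genes) and 4 lower (4 genes), and 35 passed at a threshold of 0.1. The other higher genes were Ppl, a cytoskeletal linker (log2 change 1.02 ± 0.14), Tagap, a GTPase-activating protein (0.94 ± 0.14), Ncbp2, a subunit of the nuclear cap-binding complex (0.85 ± 0.13), and Trip6, a LIM-domain protein (0.83 ± 0.12, with another probe of opposite sign). The other lower genes were Id2, an inhibitor of DNA-binding transcription factors (-0.87 ± 0.13, with another probe of opposite sign), and Man1a, a Golgi mannosidase (-0.76 ± 0.12, adjusted p = 0.0462). All 12 called probes separated the genotypes without overlap. Over all probes 1333 did so, 11.2% against 5.71% by chance, and 1358 (11.4%) had an unadjusted p below 0.05. By value only, Tef stood at 1.20, Rsph3a at 0.93 and Rdh16, a retinol dehydrogenase, at 0.77 (adjusted p = 0.0696, 0.0661 and 0.0929). On the other side Elovl3, a fatty acid elongase, stood at -0.95 (adjusted p = 0.0556), Tsc22d1 at -0.94, Hsd3b5, a steroid dehydrogenase typical of male liver, at -0.84 (adjusted p = 0.0661), Ddc at -0.80, Rnf144a at -0.75 and Hnrnpa1 at -0.68, the last with another probe of opposite sign. The liver count rested on single arrays: it was 2 without wild-type liver 1, 6 without wild-type liver 3, 24 without wild-type liver 4, 54 without mutant liver 1 and 2 without mutant liver 2 or mutant liver 3. It also moved with the processing. It was 0 with no filter on dim probes, 2 with quantile normalization over all 15 arrays, 37 with trend and robust settings and 152 in a single fit of all arrays. The sizes of dim genes rested on the background step: with a floor of 16 in place of background correction and offset, Usp2 stood at 0.87 and Alas1 at 2.25, and Ppl (0.27), Tagap (0.50), Ciart (0.24), Ncbp2 (0.22), Trip6 (0.31), Pdk4 (-0.38) and Man1a (-0.24) lost their calls. Of 19 alternative settings Man1a lost its call in 14, Ncbp2 in 12, Trip6 in 11, Tagap in 10, Ciart and Ppl in 8, Id2 and Pdk4 in 7, Rnf125 in 5 and Alas1 and Usp2 in 1.

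**Figure D1:**
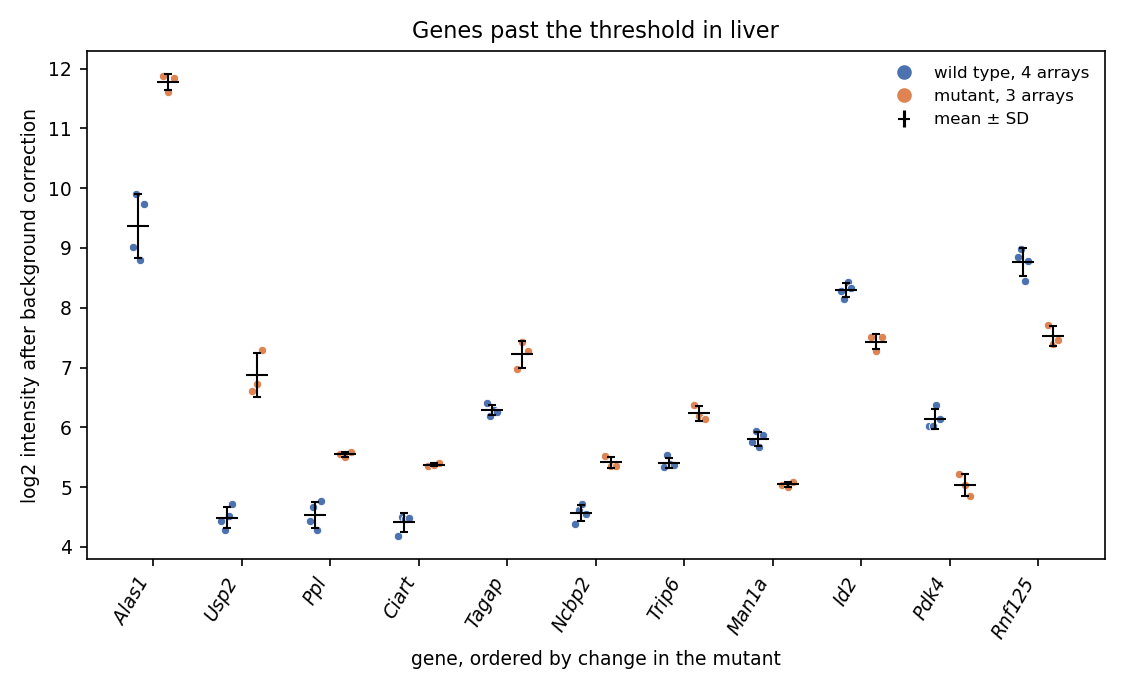
Log2 intensity after background correction (vertical axis) of the 11 genes past the threshold in liver (horizontal axis, ordered by the change), with 1 point per array (4 wild-type in blue, 3 mutant in orange) and black bars for mean ± SD. Alas1 and Usp2 show the widest gaps between genotypes, 2.41 and 2.39 on the log2 scale.

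The clock list shifted upward in the mutant livers, with members of both signs. Of 16 measured members of the clock list, 2 rose over all genes (Usp2 and Ciart), and 9 were higher and 3 lower when adjusted over the list alone. Dbp, a transcription factor driven by the clock, stood at 2.44 ± 0.45 (5.42-fold, adjusted p = 0.0929 over all genes), Tef at 1.20 ± 0.21, Per2 at 1.23 ± 0.24 and Per3 at 0.68 ± 0.14. On the other side Arntl, which encodes the activator BMAL1, stood at -0.90 ± 0.21 and Nfil3 at -0.87 ± 0.23. The test of the list gave camera adjusted p = 0.000417 (adjusted p = 0.857 with an estimated correlation).

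The heat-shock and endoplasmic-reticulum stress lists shifted upward in the mutant livers. Of 13 heat-shock genes 0 passed limma's threshold over all genes and 1 was higher when adjusted over the list alone, Hspe1, a mitochondrial chaperonin (0.64 ± 0.13). Of the 13, 11 had positive changes, with Ahsa1 at 0.56, Stip1 at 0.49 and Fkbp4 at 0.34 (list adjusted p = 0.00132, adjusted p = 0.857 with an estimated correlation). Of 18 genes of endoplasmic-reticulum and integrated stress, 0 passed either way. Positive changes were found in 16, with the glutathione-degrading Chac1 at 0.81 ± 0.23, Hyou1 at 0.50, Derl3 at 0.40 and Pdia4 at 0.43 (list adjusted p = 0.00883, adjusted p = 0.857 with an estimated correlation). The stress list lost its call without wild-type liver 3 (adjusted p = 0.0585) and without mutant liver 3 (adjusted p = 0.0753).

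The interferon-response, male-typical and acute-phase lists shifted downward in the mutant livers. Of 24 interferon-response genes 0 passed over all genes, 1 was lower when adjusted over the list alone, the chemokine Cxcl9 (-0.72 ± 0.16). Negative changes were found in 21, with Ifit3 at -0.48, Irf9 at -0.48 and Isg15 at -0.47 (list adjusted p = 0.000101, adjusted p = 0.857 with an estimated correlation). Of 18 genes of the male-typical pattern set by growth hormone, 0 passed over all genes, 3 were lower when adjusted over the list alone (Elovl3 at -0.95, Hsd3b5 at -0.84 and Selenbp2 at -1.19 ± 0.26). Of the 18, 16 had negative changes, while Cish, a feedback inhibitor of cytokine signalling, stood at 1.51 ± 0.52 (list adjusted p = 0.000370, adjusted p = 0.857 with an estimated correlation). Of 21 acute-phase and inflammation genes 0 passed either way. All but 2 had negative changes, with Itih3 at -0.44, Il1b at -0.52, Cxcl1 at -0.48 and Lcn2 at -0.34 (list adjusted p = 0.00883, adjusted p = 0.858 with an estimated correlation). Without mutant liver 1 the male-typical and acute-phase lists lost their calls (adjusted p = 0.220 and 0.379), and the acute-phase list also without wild-type liver 2 (adjusted p = 0.0941).

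Of the 43 lists tested in liver, 6 passed with camera at the preset correlation, 0 with an estimated correlation (8 and 2 lists had an unadjusted p below 0.05) and 2 with fry. The 2 with fry were the clock list, the 1 in common with camera, and the brown fat markers (fry adjusted p = 0.0481 for both), which camera did not call. Over all 35 splits of the liver arrays, the real one included, 8 gave as many camera calls as the real 6, so chance stays open for this number. The 37 lists that did not pass had adjusted p between 0.0776 and 0.899. They were ABC transporters, chromosome neighbours of Abcb5, cholesterol synthesis, lipogenesis, fatty acid oxidation under PPAR-alpha, gluconeogenesis and glucocorticoid response, xenobiotic metabolism, bile acid synthesis and transport, antigen presentation, oxidative stress, immediate early genes, cell cycle, oxidative phosphorylation, ribosomal proteins, proteasome, heme synthesis and iron, melanin pigment, the heart failure and fetal program, sarcomere, calcium handling and extracellular matrix. Also among them were the markers of hepatocytes, periportal and pericentral hepatocytes, cholangiocytes, Kupffer cells, stellate cells, endothelium, neutrophils, erythroid cells, atrium, brown and white fat, smooth muscle, thymus, lung and exocrine pancreas. The erythroid markers had an adjusted p of 0.334 in liver, with 3 of 5 members positive. Markers of T cells, B cells, cardiomyocytes, skeletal muscle, gut and kidney had too few measured members in liver (6 lists).

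The mutant hearts differed from wild type in a lipid enzyme, in matrix genes and in red-cell genes. Gdpd3, a lysophospholipase D, rose by 4.43 ± 0.20 on the log2 scale (SE, n = 4 mice per genotype, 21.6-fold, limma adjusted p = 6.28e-07). Lgals3, which encodes galectin-3, rose by 1.71 ± 0.21 (3.27-fold), Ptgds, a prostaglandin D synthase, by 1.60 ± 0.11 (3.04-fold), and Timp1, an inhibitor of matrix metalloproteinases, by 1.60 ± 0.17 (3.03-fold) with a further probe past the threshold. Hbb-bt, a beta-globin, changed by -3.06 ± 0.56 (8.37-fold lower, adjusted p = 0.0169), and Alas2, the erythroid form of the first enzyme of heme synthesis, by -2.14 ± 0.23 (adjusted p = 0.000779).

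Of the 18502 probes, 367 passed the threshold in heart, 212 higher (184 genes) and 155 lower (126 genes), of which 28 had no gene name, and 742 passed at a threshold of 0.1. Of the called probes 364 separated the genotypes without overlap. Over all probes 1858 did so, 10.04% against 2.86% by chance, and 2913 (15.7%) had an unadjusted p below 0.05. The other genes with the largest increase were 1700123O20Rik, above background in 0 of 4 wild-type hearts and all 4 mutant hearts and at least 2.81-fold higher, and Uts2b, which encodes a urotensin-related peptide (1.61 ± 0.32). They also included Fah, the last enzyme of tyrosine breakdown (2.84-fold), Ccdc68 (1.49 ± 0.15), Slc41a3, of a family of magnesium transporters (1.49 ± 0.11 and 2 further probes past the threshold), and 4933427D14Rik (1.44 ± 0.22). Among the lower genes were Abhd1 (-2.61 ± 0.22), E2f2, a cell-cycle transcription factor (-2.30 ± 0.27), Ube2l6, which conjugates ISG15 (-2.08 ± 0.29), and Erich2 (-2.02 ± 0.25). Lower, too, were Lgals4, which encodes galectin-4 (-1.99 ± 0.25), H2-T10, a class I histocompatibility gene (-1.85 ± 0.13), Fam220a (-1.80 ± 0.27) and Slc4a1, the band 3 anion exchanger of red cells (-1.76 ± 0.39, adjusted p = 0.0413). H2-T10 stood at 1.97 ± 0.70 in the mutant livers (adjusted p = 0.321). Only mutant livers 2 and 3 were high (7.57 and 8.02), while mutant liver 1 was at background (4.15), near the wild-type livers (4.20 to 4.89). The heart count was 130 (93 of them in common) with a floor of 16, which lies above the heart median of 8.04 to 8.08, in place of background correction and offset. It was 577 with an offset of 50 and 604 with trend and robust settings. It was 211 without wild-type heart 1, 198 without wild-type heart 3, 226 without mutant heart 1 and 198 without mutant heart 3, and 294 (249 of them in common) without wild-type heart 4, whose highest intensity stood apart. Slc4a1 lost its call in 11 and Uts2b in 10 of the 20 alternative settings. Some of the named genes were dim in 1 genotype, near the lowest value that the offset of 16 allows. Wild-type means were 4.66 for Ccdc68, 4.64 for 4933427D14Rik and 4.67 for Uts2b, and mutant means 4.68 for H2-T10 and 4.77 for Abhd1. The sizes of these changes thus rest on the background step and the offset.

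**Figure D2:**
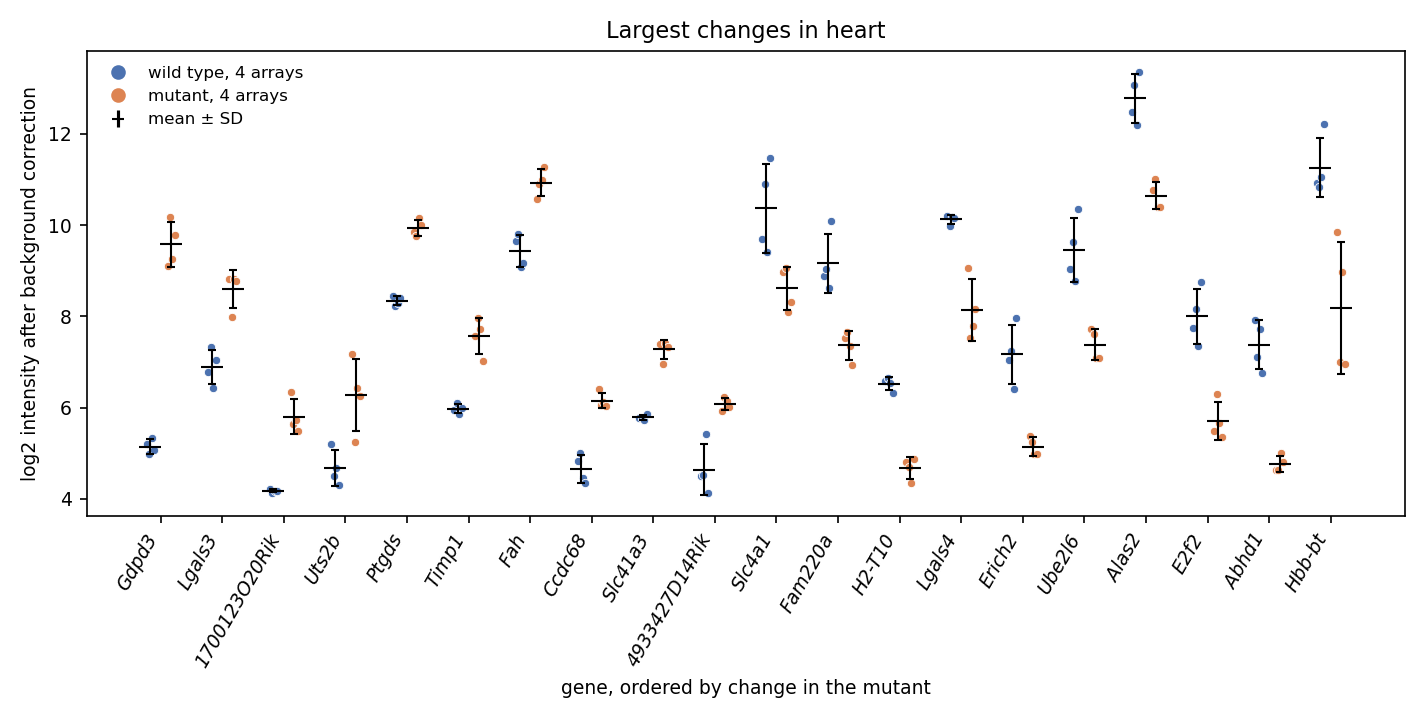
Log2 intensity after background correction (vertical axis) of the 20 named genes in heart (horizontal axis, ordered by the change), with 1 point per array (4 wild-type in blue, 4 mutant in orange) and black bars for mean ± SD. Gdpd3 shows the widest gap upward, 4.43 on the log2 scale, and Hbb-bt the widest downward, -3.06.

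The extracellular matrix list shifted upward in the mutant hearts. Of 26 measured members 10 rose over all genes and 16 were higher and 1 lower when adjusted over the list alone. Besides Timp1, at 1.55 for the probe used in the lists, Loxl1, a crosslinker of elastin, rose by 0.92 ± 0.11, Eln, which encodes elastin, by 0.94 ± 0.21, and the collagen genes Col3a1 by 0.81 ± 0.14, Col1a1 by 0.74 ± 0.13, Col5a1 by 0.75 ± 0.13 and Col15a1 by 0.64 ± 0.11. Dcn, which encodes decorin, stood at -0.27 ± 0.10 (adjusted p = 0.228). The test of the list gave camera adjusted p = 2.57e-08 (adjusted p = 0.304 with an estimated correlation). Endothelial markers moved with it: 13 of 14 had positive changes, 0 passed over all genes and 1 when adjusted over the list alone, Esam, an adhesion molecule (0.41 ± 0.10). Further members were Tie1 at 0.37, Pecam1 at 0.27 and Tek at 0.25 (list adjusted p = 0.000836, adjusted p = 0.304 with an estimated correlation). Of 12 fibroblast and stellate-cell markers 2 rose, Col3a1 and Col1a1, 3 were higher when adjusted over the list alone, and the list did not pass (adjusted p = 0.346).

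The list of the heart failure and fetal program shifted upward in the mutant hearts, with members of both signs. Of 15 measured members 3 rose over all genes and 11 were higher and 1 lower when adjusted over the list alone. Lgals3, Timp1 and Uck2, a uridine kinase (1.31 ± 0.27), were the 3, and Acta1, skeletal alpha-actin, stood at 1.42 ± 0.33 (adjusted p = 0.0514) and Nppb, which encodes the B-type natriuretic peptide, at 1.34 ± 0.31 (adjusted p = 0.0520). Members with the opposite sign, none past the threshold over all genes, were Myh7, the slow myosin heavy chain (-0.70 ± 0.19), which was the 1 lower over the list alone, Nppa, the atrial natriuretic peptide (-0.25 ± 0.17), and Comp (-0.13 ± 0.12). For the list, camera gave adjusted p = 2.92e-06 (adjusted p = 0.304 with an estimated correlation).

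The red-cell list shifted downward in the mutant hearts. Of 8 measured members of the erythroid list 4 fell over all genes, Hbb-bt, Alas2, Slc4a1 and Fech, the last enzyme of heme synthesis (-1.49 ± 0.22), and 5 when adjusted over the list alone. Hba-a1, an alpha-globin, stood at -0.43 ± 0.19 and Hbb-b2 at 0.86 ± 0.90. For this list camera gave adjusted p = 2.92e-06 (adjusted p = 0.304 with an estimated correlation). The list of fatty acid oxidation under PPAR-alpha also shifted downward: of 20 members 3 fell over all genes, 10 were lower when adjusted over the list alone and 4 had positive changes. Slc25a20, the mitochondrial carnitine carrier, changed by -0.49 ± 0.09, Acot2, an acyl-CoA thioesterase, by -0.64 ± 0.13 and the uncoupling protein Ucp3 by -0.56 ± 0.13. By value, Acadl, a long-chain acyl-CoA dehydrogenase, stood at -0.48 ± 0.11 and Angptl4, a lipoprotein lipase inhibitor, at -0.96 ± 0.25 (list adjusted p = 2.92e-06, adjusted p = 0.304 with an estimated correlation).

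**Figure D3:**
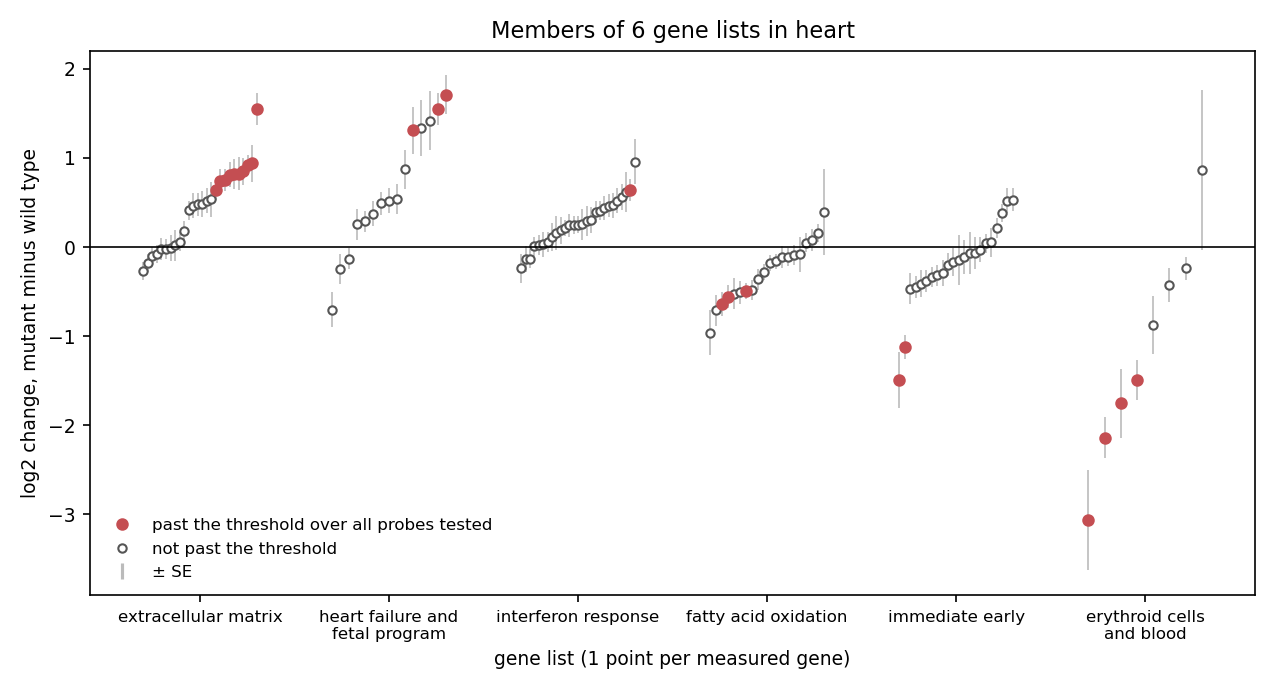
Log2 change in heart, mutant minus wild type (vertical axis), of every measured gene of 6 lists (horizontal axis), with grey bars for ± SE and filled points for genes past the threshold over all probes tested. In the extracellular matrix list 19 of 26 points lie above 0, and in the erythroid list 7 of 8 lie below.

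The interferon-response list, which shifted downward in liver, shifted upward in heart, a contrast that was not tested for the list as a whole. Of 27 members 1 rose over all genes, Oas2, an antiviral synthetase (0.64 ± 0.13), and 10 were higher when adjusted over the list alone. Of the 27, 24 had positive changes, with Usp18 at 0.56, Ifi27l2a at 0.96 and Ifi47 at 0.41 (list adjusted p = 9.82e-06, adjusted p = 0.635 with an estimated correlation). Of 16 heat-shock genes 0 passed over all genes, and 5 were higher when adjusted over the list alone. Of the 16, 14 had positive changes, with Serpinh1, a collagen chaperone, at 0.84 ± 0.21, Hsph1 at 0.92, Hspb1 at 0.46 and Hspa8 at 0.41 (list adjusted p = 0.0210, adjusted p = 0.686 with an estimated correlation). Of 22 immediate early genes 2 fell over all genes, Ccn1, a matrix-associated signalling protein (-1.12 ± 0.13), and Fos (-1.49 ± 0.31). When adjusted over the list alone 8 were lower and 3 higher, with Egr2 at 0.53 and Ccn2 at 0.52 (list adjusted p = 0.0397, adjusted p = 0.635 with an estimated correlation). Of 8 chromosome neighbours of Abcb5 3 fell, Zfp386 (-1.03 ± 0.09), Esyt2 (-0.52 ± 0.09) and Rapgef5 (-0.96 ± 0.18), the same 3 when adjusted over the list alone. Wdr60 stood at 0.18 (list adjusted p = 0.0397, adjusted p = 0.540 with an estimated correlation). Single arrays decided the last 3 lists: adjusted p was 0.0822 for heat shock, 0.0696 for the immediate early genes and 0.115 for the neighbours without wild-type heart 2. It was 0.160 and 0.0611 for the first pair without mutant heart 1, 0.0507 for the neighbours without mutant heart 2, 0.0606 for both the immediate early genes and the neighbours without mutant heart 3, and 0.289 for the immediate early genes without wild-type heart 4.

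Clock genes changed in the mutant hearts without a common direction. Of 16 members 5 rose over all genes, Nr1d1, a repressor of Arntl (1.30 ± 0.17), Ciart (0.88 ± 0.12, and 1.29 ± 0.15 on the probe used in liver), Dbp (0.67 ± 0.14), Bhlhe40 (0.58 ± 0.13) and Clock (0.47 ± 0.10), and 1 fell, Nfil3 (-0.46 ± 0.10). Adjusted over the list alone 5 were higher and 5 lower, and the list as a whole did not pass (adjusted p = 0.678, with a negative median and an upward test).

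**Figure D4:**
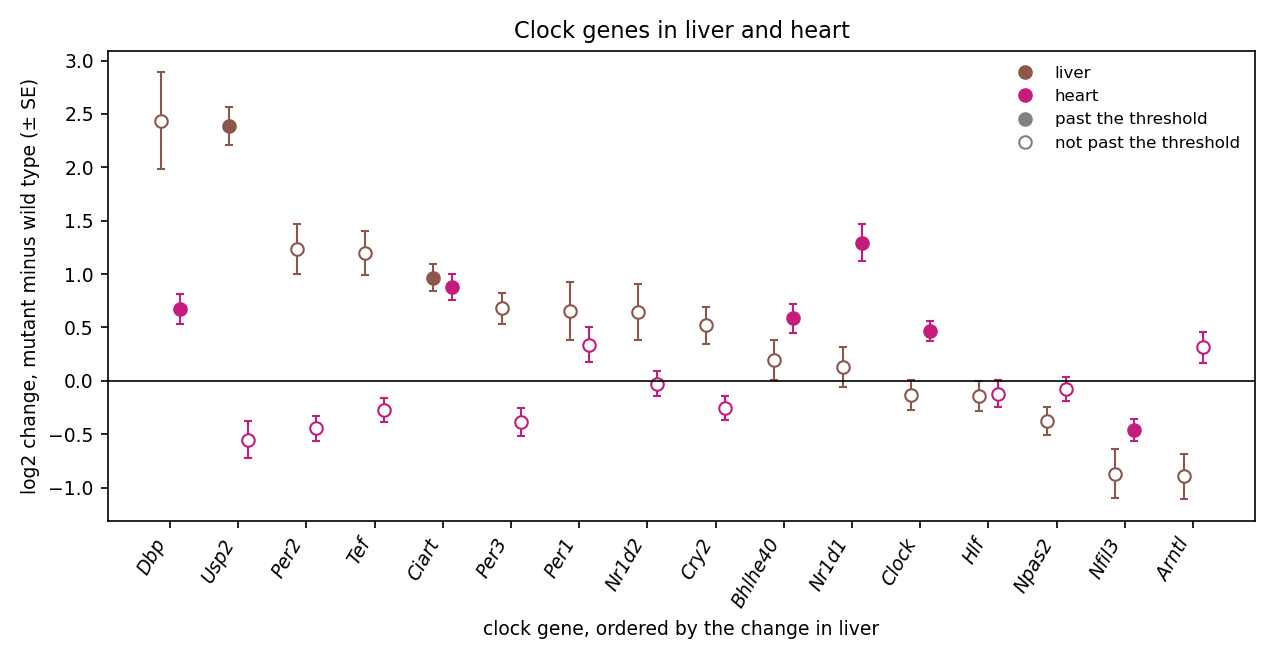
Log2 change, mutant minus wild type (vertical axis), of the 16 clock genes measured in both tissues (horizontal axis, ordered by the change in liver), in liver (brown) and heart (magenta) with bars for ± SE and filled points past the threshold. Ciart is filled in both tissues, at 0.97 in liver and 0.88 in heart, on different probes (1.29 in heart on the liver probe), and Usp2 lies at 2.39 in liver and -0.55 in heart.

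Of the 49 lists tested in heart, 9 passed with camera at the preset correlation, 0 with an estimated correlation (12 and 5 lists had an unadjusted p below 0.05) and 6 with fry. Over all 35 splits of the heart arrays, the real one included, 5 gave as many camera calls as the real 9, so chance stays open for this number. The 40 lists that did not pass, the clock and fibroblast lists included, had adjusted p between 0.0840 and 0.964. The rest were ABC transporters, cholesterol synthesis, lipogenesis, gluconeogenesis and glucocorticoid response, xenobiotic metabolism, bile acids, the male-typical pattern, acute phase, antigen presentation, endoplasmic-reticulum stress, oxidative stress, cell cycle, oxidative phosphorylation, ribosomal proteins, proteasome, heme synthesis and iron, melanin pigment, sarcomere and calcium handling. Also among them were the markers of hepatocytes, periportal and pericentral hepatocytes, cholangiocytes, macrophages, T cells, B cells, neutrophils, cardiomyocytes, atrium, brown and white fat, skeletal muscle, smooth muscle, thymus, lung, exocrine pancreas, gut and kidney. In 6 of these lists in heart and 3 in liver the median and the test differed in sign, and in 4 and 2 the mean and the test did.

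The genotype effect itself differed between the tissues for genes above background on most arrays of both. Usp2 differed by 2.94 ± 0.26 on the log2 scale as the liver change minus the heart change (limma adjusted p = 2.07e-05, n = 15 arrays), with 2.39 in liver and -0.55 in heart. Alas1 differed by 2.20 ± 0.27, with 2.41 in liver and 0.21 in heart. Creb3l2, a stress-related transcription factor, differed by -1.80 ± 0.20, with -0.59 in liver and 1.21 in heart, and Rnf125 by -1.49 ± 0.18, with -1.24 in liver and 0.25 in heart.

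Of 19570 probes 311 passed for the tissue difference, 162 with the higher change in liver and 149 with the higher change in heart, and 530 passed at a threshold of 0.1. Of the 311 probes 234 were above background on at least 3 arrays in both tissues, 65 in heart only and 12 in liver only. The other named genes were above background on 3 or fewer of the 7 liver arrays, so their values mainly restate the change in heart: Gdpd3 (-4.46 ± 0.25, adjusted p = 3.70e-08), Ptgds (-1.50 ± 0.15), Slc41a3 (-1.45 ± 0.14), Angptl7 (1.65 ± 0.23), Stk35 (1.63 ± 0.22) and Hbq1a, a globin (1.62 ± 0.22). With a floor of 16 in place of background correction and offset the count was 410, 179 higher in liver and 231 higher in heart, with 213 in common, and with quantile normalization in addition it was 427, 183 and 244. With background correction and quantile normalization over all 15 arrays, the setting nearest the plan, the count was 248 (217 in common), 122 and 126. With the mouse as a fixed block, which also leaves out mutant heart 4 (228 without that array alone), the count was 147, 68 and 79, so the near-even balance of directions was not stable. The count was 187 without wild-type liver 1, 202 without wild-type liver 2, 185 without mutant liver 3, 191 without wild-type heart 1, 194 without wild-type heart 3, 159 without mutant heart 1 and 178 without mutant heart 3.

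The changes in liver and heart were close to uncorrelated. Across 11415 probes tested in both tissues the changes correlated at r = -0.0148 (Pearson) and -0.0128 (Spearman), across genes, which are not independent replicates. In the 7 mice with both tissues they correlated at -0.00802 and 0.00448, and reassigning the genotypes over all 35 splits gave exact two-sided permutation p = 0.743 and 0.914, and the smallest p this design allows is 0.0286. Of these probes 12 passed in liver and 272 in heart. The 2 that passed in both, both for Ciart and both higher, compare with 0.286 for independent lists. Among the 500 probes of smallest p in each tissue 40 overlapped, against 21.9 for independent lists, and 17 of them had the same sign. In the 7 mice with both tissues 16 had the same sign, and 9 of the 35 splits gave as many (highest other 24).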

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

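Of the tests below, those of the clock genes in both tissues, of the genes near Abcb5, of inherited differences in the same mice and of faulty beads, and for crossed mouse labels the interval and the counts of low values, were chosen only after the result was seen.

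The genotype effect differed between liver and heart, by the test of the difference itself, for 35 of the 44 named genes. These were chosen for large changes or small p, some of them for this difference, and over all probes 311 of 19570 passed. As the liver change minus the heart change on the log2 scale, values above 0 were found for H2-T10 (3.82), Hbb-bt (3.03), Usp2 (2.94), E2f2 (2.504), Alas2 (2.44), Alas1 (2.20), Ube2l6 (2.08), Fam220a (1.85), Lgals4 (1.77), Abhd1 (1.70), Tef (1.48), Ppl (1.08), Trip6 (0.89) and Ncbp2 (0.67). Values below 0 were found for Lgals3 (-1.86), Creb3l2 (-1.80), Rnf125 (-1.49), Fah (-1.41), Id2 (-1.08), Rnf144a (-1.06) and Hnrnpa1 (-0.79). The liver side of H2-T10 rested on mutant livers 2 and 3, since mutant liver 1 was at background. Above background on 3 or fewer of the 7 liver arrays were Gdpd3 (-4.46), 4933427D14Rik (-1.50), Slc4a1 (2.11), Angptl7 (1.65), 1700123O20Rik (-1.79), Uts2b (-1.64), Timp1 (-1.60), Ptgds (-1.50), Slc41a3 (-1.45), Erich2 (2.05), Stk35 (1.63) and Hbq1a (1.62), and on 1 of the 8 heart arrays Elovl3 (-1.01) and Hsd3b5 (-0.95), so these values do not compare measured changes in 2 tissues.

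A single array lay far from the other 3 of its group in 11 of 171 groups of values (6.43%), and chance flags about 1 in 20 groups. The gap to the nearest other array, as a share of the group's range, was 0.943 for Lgals3 (mutant heart 2 at 7.98 against 8.78 to 8.83), 0.893 for Col5a1 (mutant heart 4 at 8.79 against 9.11 to 9.15) and 0.923 for the mean of the extracellular matrix list (mutant heart 4 at 8.84 against 9.09 to 9.11). Among the wild-type hearts it was 0.963 for Acot2 (heart 3 at 8.03 against 7.45 to 7.48), 0.962 for Usp18 (heart 3 at 6.18 against 6.01), 0.881 for Tek (heart 4 at 8.77 against 8.96 to 8.98) and 0.930 for the highest intensity (heart 4 at 55709.9 against 27839.7 to 29793.5). Among the wild-type livers it was 0.978 for Cxcl9 (liver 2 at 7.76 against 7.501 to 7.507), 0.924 for Selenbp2 (liver 2 at 10.62 against 9.953 to 10.004), 0.920 for Ciart (liver 1 at 4.18 against 4.47 to 4.50) and 0.868 for the highest intensity (liver 2 at 18221 against 20416.7 to 20749.7).

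Whether the counts arise from any split of the arrays was tested by reassigning the genotypes over all 35 splits, the real split included. In heart 1 split gave as many called probes as the real 367 (highest other 8), and for the tissue difference 1 split gave as many as the real 311 (highest other 3), which argues against chance for both counts. In liver 2 splits gave as many as the real 12 (highest other 12), 8 splits gave as many called gene lists as the real 6 (highest other 10), and in heart 5 splits gave as many called lists as the real 9 (highest other 15). Chance therefore stays open for the number of probes called in liver and for the number of gene lists called in either tissue. The other liver split with 12 called probes was the real split with wild-type liver 4 moved to the mutant livers. That split still kept the mutant livers together, so it is close to the grouping by genotype. Why wild-type liver 4 went with the mutant livers there was not tested, and its genotype label was not checked.

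Clock genes differed between genotypes in liver and in heart, but not in the same way. Against a single sampling-time difference shared by both tissues of the same mice, 7 of 16 clock genes had opposite signs in the tissues with a tissue difference past the threshold over the list alone, 5 of them over all genes (Usp2, Tef, Per2, Per3 and Arntl), and the changes correlated at -0.0451 across these genes, which are not independent replicates. Of the 6 clock genes called in heart, Nr1d1, Ciart, Dbp, Bhlhe40 and Nfil3 had the same sign in liver, and Clock did not. Usp2, Tef, Per2, Per3 and Arntl did not pass over all genes in heart. There Usp2 stood at -0.55 (limma adjusted p = 0.134) and Tef at -0.28 (limma adjusted p = 0.260). The values therefore argue only in part against a shared difference. An effect of the mutation, a difference between the mice in other respects than genotype, and a sampling-time difference that the clocks of the tissues show differently, stay open and were not tested. A sampling-time difference also stays open if the livers and hearts came from other mice than labelled, which was not tested.

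Genes called in heart lay beside each other in gene order more often than in random sets. Near Abcb5, 4 of 51 measured genes were called (Tnfaip2, Zfp386, Esyt2 and Rapgef5), 7.84% against 2.45% elsewhere (one-sided Fisher exact p = 0.0369, odds ratio 3.39, 95% interval 0.881 to 9.36). Of these, 3 belong to the list of neighbours whose calls had been seen before this test was chosen. Without that list's members 1 of 44 was called (2.27% against 2.45% elsewhere, one-sided Fisher exact p = 0.665, odds ratio 0.926, 95% interval 0.0228 to 5.48). DNA inherited with the mutation around Abcb5 therefore stays open. The first count includes calls already seen. The second leaves out genes listed as neighbours of Abcb5, so it cannot test the DNA at those genes, and it rests on too few others. Away from Abcb5 there were 14 adjacent called pairs (random median 7, 95th percentile 12, permutation p = 0.0177 over 10000 random sets), and 11 without pairs of similar names (95th percentile 11, permutation p = 0.0754). DNA differences between the mice elsewhere and neighbouring members of one gene family therefore both stay open, and an effect of the mutation itself on these genes was not tested.

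Strongly varying genes did not keep their order of mice between liver and heart. With the means of each genotype taken out, the labelled pairs of the 7 mice correlated at a mean of -0.197 over 19 probes. The 95% interval over probes was -0.363 to -0.0414, and 132 of 144 pairings within genotype were as high. Intervals over probes take the probes as independent, but some neighbouring genes moved together within groups. The absolute correlation was 0.951 in liver and 0.999 in heart for Atf4 and Tomm22, and 0.994 and 0.962 for Slc25a17 and Atf4. The intervals can thus be too narrow. With genotype left in, the mean was -0.104 over 26 probes. If each liver and heart came from the labelled mouse, these values argue against inherited differences seen in both tissues of the same 7 mice. With wrong labels such differences could also give low correlations. With mouse labels crossed between the tissues, the best pairing reached 0.260 (upper end of the 95% interval over probes 0.420, shuffled median 0.249, 95th percentile 0.324), below the bound of 0.5 set beforehand. The number of mice with low values, which needs no pairing, was the same in both tissues for 5 of the 26 probes and 1 of the 8 widest-ranging. The bound of 0.5 was dropped after the result was seen, because shuffled values stay below it too, and later taken up again with the interval and the counts. The 8 widest-ranging probes alone reached 0.562 (shuffled 95th percentile 0.564). No pairing of these mice went beyond the shuffled values. Crossed labels could show only if these probes varied alike in both tissues of a mouse, so crossed labels stay open. Against faulty beads at single probes, neighbouring varying genes moved together within groups, with a median absolute correlation of 0.708 in heart (random 95th percentile 0.559) and 0.633 in liver (random 95th percentile 0.542). These were 14 pairs among 92 varying genes in heart and 16 among 95 in liver, not the 26 probes as a set. Faulty beads stay open for probes with no such neighbour. Livers and hearts from other mice than labelled were not tested.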

How the results depend on the processing

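All alternatives below were planned except the quantile normalizations of background-corrected values. Quantile normalization was planned for the main values, and was run as an alternative only after the data were seen. With a floor of 16 in place of background correction and offset, 5 probes passed in liver and 130 in heart, where the floor lies above the median, and with quantile normalization in addition 5 and 137. With an offset of 50 the heart count was 577, and with quantile normalization over all 15 arrays the counts were 2 in liver and 559 in heart. Quantile normalization within the tissue, as planned for the genotype tests, gave 12 in liver and 369 in heart. Over all 15 arrays, as planned for the tissue difference, it gave 248 for that difference (217 in common). With no filter on dim probes limma called 0 in liver (2064 had an unadjusted p below 0.05), where more probes were tested. With trend and robust settings the counts were 37 in liver and 604 in heart, and in a single fit of all 15 arrays 152 and 574. Camera with an estimated correlation called 0 lists in liver and 0 in heart, and fry called 2 in liver. The cause was not tested for these.

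With 1 array left out, which leaves fewer samples, the count ranged from 2 to 54 in liver, from 198 to 294 in heart and from 159 to 302 for the tissue difference, the number of lists from 5 to 9 in liver and from 7 to 9 in heart, and the correlation of the changes between tissues from -0.0503 to 0.00517. The replicate block, by replicate numbers that wild-type and mutant mice share without being the same mice, gave 32 probes in liver (7 of them in common) and 237 in heart (216 in common), in liver also taking out wild-type liver 4, the only one numbered 4 (24 without that array alone), and the list of Abcb5 neighbours in heart ended at an adjusted p of 0.0547. Same-numbered mice deviated at correlations of -0.0433 to 0.0141 in liver and -0.106 to -0.0506 in heart, and 0 mutants correlated best with their own number. The mouse as a fixed replicate block gave 147 for the tissue difference (127 in common), also leaving out mutant heart 4 (228 without that array alone), and no replicate block gave 310. The fixed block changed no call of a gene named for the difference.

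No named gene or list reversed. Apart from leave-one-out, values of named genes kept their side of the threshold in 177 cases in liver (42 weaker, 21 stronger), 210 in heart (30 weaker) and 120 for the tissue difference. Called lists kept theirs in 67 cases in liver (11 lost) and 99 in heart (18 lost). In heart the heat-shock list ended at an adjusted p of 0.0555 with the floor of 16, and the immediate early list at 0.0523 with no filter, 0.0532 with the strict filter and 0.101 with array weights. The share of higher calls in liver was 66.7%, and 45.9% with trend and robust settings. A slide block was not run. Fewer probes rose above background in liver (45.9% to 46.0%) than in heart (67.3% to 67.4%).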

Other observations

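The tests in this part were planned, but the genes named were picked after their values were seen, from lists fixed beforehand that did not pass as lists. In the mutant hearts Cdkn1a, a cyclin-dependent kinase inhibitor, rose by 1.31 ± 0.21 (limma adjusted p = 0.00778), and the proteasome subunit genes Psmb1 and Psmb5 rose by 1.23 ± 0.13 (adjusted p = 0.000779) and 0.96 ± 0.16 (adjusted p = 0.00973), 2 of 24 measured proteasome genes. Chac1, a stress-induced enzyme of glutathione breakdown, rose by 1.13 ± 0.22 (adjusted p = 0.0205), Cish by 0.65 ± 0.11 (adjusted p = 0.0138), Slc51a, part of a bile acid transporter, by 0.51 ± 0.11 and the histocompatibility gene H2-T23 by 0.54 ± 0.11. Rpl22, a ribosomal protein gene, changed by -0.40 ± 0.09 (adjusted p = 0.0398).

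In liver several metabolic genes stood past the threshold only when adjusted over their list alone. Cyp4a14, a fatty acid hydroxylase under PPAR-alpha, stood at 2.51 ± 0.50 (adjusted p = 0.113 over all genes, 0.00369 over the list), Ppargc1a, a coactivator of mitochondrial genes, at 0.71 ± 0.15 (0.0103 over the list), Acaca, the acetyl-CoA carboxylase of fatty acid synthesis, at 0.62 ± 0.15 (0.0301 over the list) and Insig1, a brake on sterol synthesis, at -0.85 ± 0.20 (0.0259 over the list). Of 24 ABC transporter genes measured in each tissue 0 passed limma's threshold over all genes or over the list alone, and Abca3 stood at -0.97 ± 0.26 in liver (adjusted p = 0.211 over all genes).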
